A study of Xenopus laevis with 25 samples.

How the data were processed

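The authors' deposited abundance tables give, for each of the 25 libraries, the estimated counts that kallisto assigned to 22891 transcripts, per the submitters' processing notes. The same deposited tables hold transcript lengths, effective lengths and TPM, which the authors obtained from kallisto and which served here only as a check of the units. The authors' deposited comparison tables, made with sleuth for each hour per the submitters' processing notes, hold p-values, q-values, variance components and effects on the natural log scale. The column names give no arm. Across the more abundant transcripts these natural log effects matched wild type minus morpholino in the counts (r from 0.9999 to 0.99998 over the hours). They were turned to log2 morpholino minus wild type. The kallisto and sleuth versions, the options and the transcriptome build were not given in the sources used here.

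The transcript identifiers have the prefix of Xenopus tropicalis while the labels name Xenopus laevis. Symbols were taken from the authors' deposited comparison tables, and 14700 of the 16967 tested transcripts had one. If the embryos were Xenopus laevis, reads from both copies of a duplicated gene were counted on a shared transcript. Between 26.6% and 31.1% of the estimated counts in a library were not whole, and counts were rounded to whole numbers. Effective lengths were identical in all libraries, so no length offset was used.

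The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and jsonlite 2.0.0. Transcripts were filtered by edgeR's filterByExpr with the 10 groups (arm by hour), which left 16967 of 22891 (74.1%), and scaled by TMM. Counts were fitted by edgeR's quasi-likelihood model with trended dispersions, and p values were adjusted by Benjamini-Hochberg within each comparison. The average effect is the mean of the 5 hourly differences, each arm's change over time is a straight line through its 5 hours, and the difference between hours is a joint test on 4 contrasts. SE denotes the fitted log2 change divided by the root of its F statistic, and SD is taken over libraries. A transcript was called at an adjusted p under 0.05.

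The 21 gene lists were tested by limma camera with a fixed correlation of 0.01 between genes, and again with an estimated correlation and with fry. Lists share members: 13 of the 27 endoderm transcripts are also on another list, and 0 of the 38 on the p53 list. Named genes are the targeted gene and its partner, the genes fixed for cilia, left-right and heart development, and the 4 transcripts of each list with the smallest p. To these come, among symbols with an average of at least 1 log2 CPM, the 10 largest rises and falls with the same sign at all 5 hours, the 3 largest at each hour with no overlap between arms, the 5 largest wild-type slopes each way and the 5 smallest p for a difference between hours. Some of the genes this rule selects are not reported here. The stage index projects each library on the wild-type change over time, leaving a wild-type library out of its own line, and tests the arms by exact permutation within hours. The comparisons, gene lists, thresholds and most alternatives were chosen before the data were examined, and the alternatives without morpholino replicate 3, against earlier wild type, at 14 to 16 hpf only, on 5 sums, with a block per arm and with thinned counts were chosen afterwards.

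A simulation on the same design checked each comparison, with libraries drawn independently around a common mean. It held no deviations shared by same-numbered libraries and no replicate that stood apart, so its rates need not hold for these data. For the average effect it recovered 24% of transcripts changed by 1.5-fold and 82% of those changed by 2-fold, and it called 0.0248% of unchanged ones. At 14 hpf it recovered 0% and 3%, so an hour taken alone detects few changes of that size. Slopes of 0.5 log2 units per hour were recovered for 75% of transcripts in wild type and 82% in the morpholino arm, and slopes of 0.25 for 13% in wild type. The test of differences between hours called 0 transcripts where none differed. The list test called 1 list, the list that had been lowered, and the stage index placed libraries simulated 1 hour late at -0.792 hours.

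The labels do not say that replicates came from separate clutches or batches, so the p values measure the spread between these samples alone. After removing the mean of each group, same-numbered wild-type libraries correlated over transcripts at 0.103 to 0.172 in all 10 pairs of hours (with 2 libraries per hour the deviations mirror each other, so both numbers give the same values), so the replicate number pairs the wild-type time course. Morpholino libraries correlated in the same way at 0.25 to 0.535 for number 3, 0.124 to 0.426 for number 1 and 0.0274 to 0.189 for number 2 (7 of 10 pairs over 0.1). Wild-type and morpholino libraries of the same number and hour correlated at -0.0586 to 0.185. Over any hours the number 1 libraries of the 2 arms correlated at 0.0542 to 0.249 and the number 2 libraries at -0.106 to 0.0702, so a pairing of the arms is not excluded for number 1. The fits treat the libraries as independent, and the values with the replicate number as a block are given with the comparisons. A block over both arms assumes that numbers 1 and 2 pair across the arms. Number 3 occurs only in the morpholino arm, so the block takes up its mean level. The blocked average difference between the arms therefore rests on numbers 1 and 2.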

Results

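Poly(A)-selected RNA from Xenopus embryos was profiled at 12, 13, 14, 15 and 16 hours post fertilization (hpf), the hours around gastrulation and neurulation, in 10 wild-type libraries (2 per hour) and 15 libraries from embryos given an RNF20 morpholino (3 per hour). A morpholino is a synthetic antisense oligomer that blocks the translation or splicing of its target transcript. RNF20 is the ubiquitin ligase that, with its partner RNF40, attaches ubiquitin to histone H2B, and the series title ties this mark to cilia motility and heart development. The comparisons below ask which transcripts differed between the arms and how each arm changed over the 5 hours. Library totals ran from 12.8e6 to 36.2e6 estimated counts, and 16967 transcripts were tested. The 5 libraries of morpholino replicate 3 stood apart at each hour: mitochondrial transcripts took 2.31% to 2.89% of their counts, 1.33% to 1.89% in the other morpholino libraries and 1.16% to 1.4% in wild type. At each hour this share was higher in each morpholino library than in each wild-type library. At 16 hpf replicate 3 correlated with the other morpholino libraries at r = 0.843 and 0.860 across transcripts (log2 CPM, counts scaled to library size), where those correlated with each other at 0.963. Transcripts are not independent replicates, so these coefficients only describe the libraries.

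The targeted transcript, rnf20, was not lower in the morpholino libraries. It averaged 61.7 ± 13.5 CPM (SD, n = 10) in wild type and 75.6 ± 11.9 CPM (SD, n = 15) in the morpholino arm, a log2 change of 0.31 ± 0.09 (SE, edgeR quasi-likelihood adjusted p = 0.020). By hour the log2 difference was 0.92, 0.54, 0.13, 0.18 and -0.20 from 12 to 16 hpf. Its partner rnf40 rose by 0.50 ± 0.09 (SE, edgeR adjusted p = 0.0012) and stood at 0.42 against wild type 2 hours earlier (adjusted p = 0.0728). A morpholino need not lower its target's RNA, so these levels check neither the labels nor the knockdown. The rnf20 call ended without the libraries at 12 hpf (0.18, edgeR adjusted p = 0.198), at 13 hpf (0.26, adjusted p = 0.113) and over 14 to 16 hpf alone (0.04, adjusted p = 0.878), and its adjusted p ran from 0.00368 to 0.878 over all alternatives.

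Averaged over the 5 hours, 13 of 38 transcripts on the p53 list rose, and a few other transcripts shifted at each hour. Cyclin G1 (ccng1), a p53 target, went from 146 ± 34.5 CPM (SD, n = 10) in wild type to 547 ± 136 CPM (SD, n = 15), a log2 rise of 1.91 ± 0.11 (SE, edgeR quasi-likelihood adjusted p = 3.08e-08). Each of the 15 morpholino libraries (lowest 346 CPM) exceeded each of the 10 wild-type libraries (highest 205.3 CPM). The p53 target eda2r rose by 2.93 ± 0.27, the apoptosis-enhancing nuclease aen by 1.41 ± 0.12 and mdm2, the ligase that degrades p53, by 0.76 ± 0.10 (SE, edgeR adjusted p = 2.7e-06, 1.21e-06 and 1.1e-04). Of the 38 tested transcripts on the list of p53 targets and cell death, 13 rose and 2 fell (14 and 2 adjusted over the list alone). The list rose in camera (adjusted p = 0.0058), with adjusted p = 0.412 with an estimated correlation. Without morpholino replicate 3 its camera adjusted p was 0.00817 (from 2.59e-05 to 0.412 over all alternatives), with adjusted p = 0.0732 with an estimated correlation, and 12 of those 13 transcripts still passed.

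Outside that list, rpap3, a co-chaperone in the assembly of RNA polymerase II and other complexes, fell by 2.01 ± 0.13 on the log2 scale (SE, edgeR adjusted p = 5.09e-08), from 60.9 ± 2.91 CPM (SD, n = 10) to 15.2 ± 3.88 CPM (SD, n = 15). The cytoskeletal adaptor pdlim7 fell by 1.55 ± 0.10 and the nuclear lamin lmnb3 by 0.97 ± 0.07, while the kinase riok3 rose by 1.54 ± 0.11 (SE, edgeR adjusted p = 3.72e-08, 9.03e-08 and 1.4e-07). The morpholino and wild-type libraries did not overlap for any of these 4 transcripts. A transcript of dedd, a death effector domain protein, rose by 3.57 ± 0.28 and a transcript of cxxc1, which binds unmethylated CpG sites, by 2.53 ± 0.17 (SE, edgeR adjusted p = 3.51e-07 and 9.03e-08). Dedd has 2 tested transcripts and cxxc1 has 4, and with counts summed per symbol the changes were 1.41 and 0.42.

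**Figure D1:**
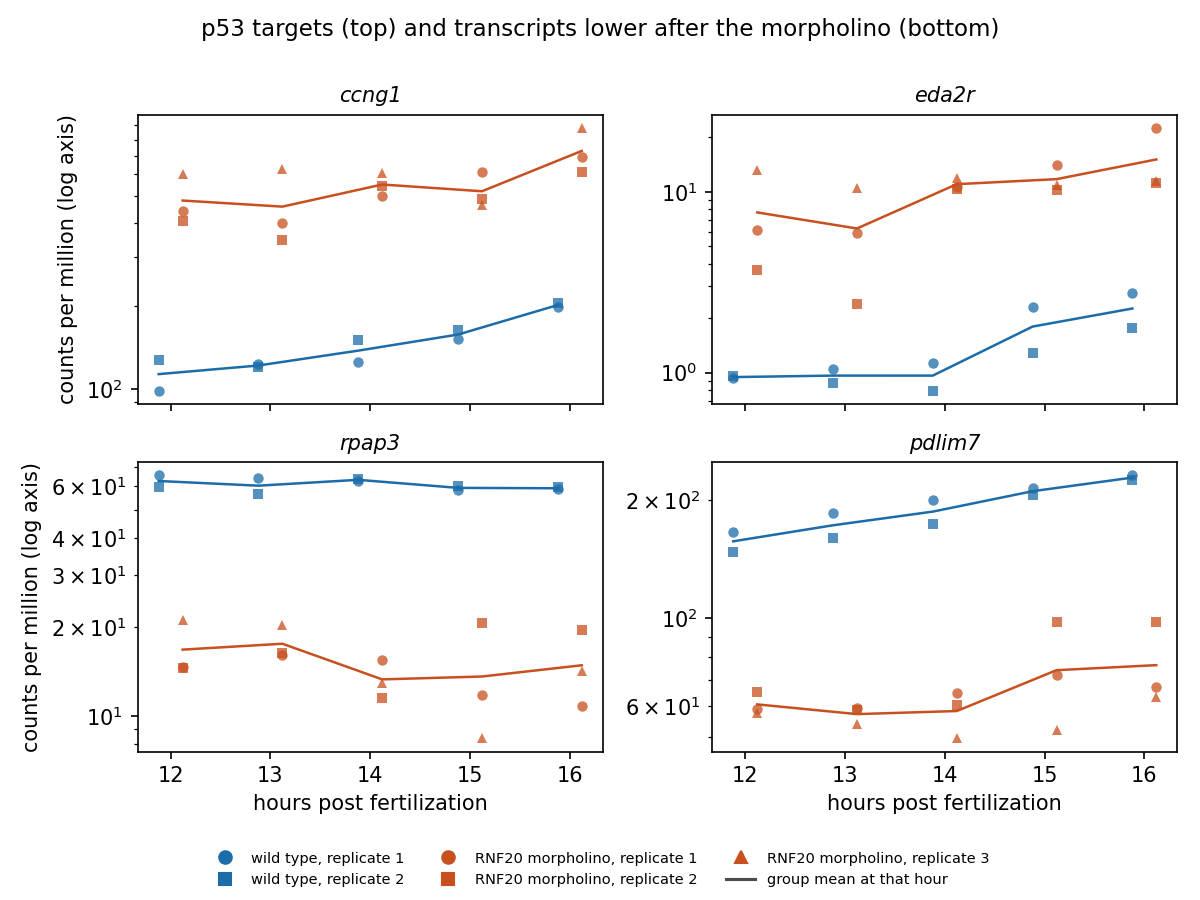
CPM (log axis) against hours post fertilization for the p53 targets ccng1 and eda2r and for rpap3 and pdlim7, with a point per library (shape gives the replicate number) and a line through the group mean at each hour; 2 wild-type and 3 morpholino libraries stand at each hour. All 15 morpholino libraries lie above the wild-type libraries for ccng1 (346 CPM or more against at most 205.3 CPM) and below them for rpap3 (at most 21.1 CPM against 56.5 CPM or more).

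Camera called 2 lists of axonemal transcripts lower in the morpholino arm and a list of multiciliated cell regulators higher, and each call was lost with an estimated correlation. Of 79 tested transcripts for the nexin link, radial spokes, central pair and doublet proteins, 17 fell and 1 rose, with the same counts adjusted over the list alone. The list fell in camera (adjusted p = 4.52e-05, with as small a p in 35 of 100 redraws of the arm labels), with adjusted p = 0.619 with an estimated correlation. Among them tcte1, of the nexin link, fell by 1.05 ± 0.19, CFAP43 by 0.93 ± 0.18 and efhc2 by 0.92 ± 0.20 on the log2 scale (SE, edgeR adjusted p = 0.00144, 0.00198 and 0.00376). Of 26 transcripts for axonemal dynein arms and their docking, 4 fell and 1 rose, also adjusted over the list alone. These dynein transcripts fell as a list in camera (adjusted p = 0.0277, with as small a p in 43 of 100 such redraws), with adjusted p = 0.645 with an estimated correlation. The dynein intermediate chain wdr78 fell by 0.81 ± 0.14, from 22.5 ± 2.47 CPM (SD, n = 10) to 12.8 ± 3.23 CPM (SD, n = 15), and the docking gene ccdc63 fell by 0.76 ± 0.14 (SE, edgeR adjusted p = 7.95e-04 and 0.00142). The outer arm heavy chain dnah5 stood at -0.52 ± 0.22 (SE, edgeR adjusted p = 0.0818), passing with an adjusted p of 0.034 without morpholino replicate 1 at 12 hpf and 0.0458 without replicate 1 at 16 hpf. The dynein arm list lost its call without all of morpholino replicate 3 (camera adjusted p = 0.308, from 0.0041 to 0.681 over all alternatives), without wild-type replicate 1 at 13 hpf (0.0531) and without morpholino replicate 3 at 14 hpf (0.0519). The nexin link and spoke list passed without replicate 3 (camera adjusted p = 0.0105, from 1.52e-06 to 0.619 over all alternatives), with adjusted p = 0.801 with an estimated correlation. This list was not called against wild type 2 hours earlier (camera adjusted p = 0.233), where 0 of its 17 fallen transcripts were still called (median -0.322, with 1 still called and a median of -0.572 against wild type of the same hour at 14 to 16 hpf) and tcte1 stood at -0.32, CFAP43 at -0.70, efhc2 at -0.58, wdr78 at -0.67 and ccdc63 at -0.47 (edgeR adjusted p from 0.0565 to 0.614). It was not called either against wild type 1 hour earlier without replicate 3 (camera adjusted p = 0.113). With all libraries and wild type 1 hour earlier, tcte1 (-0.78), CFAP43 (-0.80), wdr78 (-0.72) and ccdc63 (-0.62) stayed called, and efhc2 (-0.74) did not. Their edgeR adjusted p ran from 0.00963 to 0.0521.

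Among 39 transcripts for ciliary and multiciliated transcription and centriole amplification, 11 rose and 2 fell, also adjusted over the list alone. This list rose in camera (adjusted p = 0.0496, with as small a p in 21 of 100 redraws of the arm labels), with adjusted p = 0.607 with an estimated correlation. MCIDAS, which switches on the multiciliated programme, rose by 1.95 ± 0.35, ccno by 1.91 ± 0.40 and deup1, a scaffold for centriole amplification, by 1.07 ± 0.18 (SE, edgeR adjusted p = 0.00109, 0.00328 and 8.7e-04). With wild type 2 hours earlier as the reference MCIDAS stood at 0.18, ccno at 0.59 and deup1 at 0.47 (edgeR adjusted p = 0.905, 0.636 and 0.382), and the list turned down (camera adjusted p = 0.526). The risen list member pcm1, a centriolar satellite gene, stayed called in that comparison (0.63, edgeR adjusted p = 4.38e-04). MCIDAS averaged 14.6 ± 15.9 CPM (SD, n = 10) in wild type, where it fell steeply over the hours, and 33.6 ± 16.0 CPM (SD, n = 15) in the morpholino arm. The ciliary master regulator foxj1 stood at 0.36 ± 0.12 (SE, edgeR adjusted p = 0.0392), a call that 14 of the 25 omissions of a library ended (adjusted p up to 0.094). The foxj1 call also ended without morpholino replicate 3 (0.17, edgeR adjusted p = 0.0543) and against wild type 2 hours earlier (0.22, adjusted p = 0.583). A transcript of rfx2 rose by 0.81 ± 0.23 (SE, edgeR adjusted p = 0.0184, and 0.0516 without wild-type replicate 1 at 12 hpf). This call also ended against wild type 1 hour earlier (0.78, edgeR adjusted p = 0.0839) and 2 hours earlier (0.49, adjusted p = 0.498). It ended too against wild type of the same hour at 14 to 16 hpf (0.67, edgeR adjusted p = 0.156). The more abundant rfx2 transcript stood at 0.05 ± 0.13 (SE, adjusted p = 0.836) and counts summed per symbol at 0.08 (adjusted p = 0.62). The more abundant of 2 rfx3 transcripts stood at -0.97 ± 0.53 (SE, edgeR adjusted p = 0.171), and with counts summed per symbol rfx3 stood at -0.95 (adjusted p = 0.00973). The list call itself ended without all of morpholino replicate 3 (camera adjusted p = 0.129, from 0.0011 to 0.733 over all alternatives). It also ended, at adjusted p from 0.0502 to 0.0759, without wild-type replicate 1 at 12, 14, 15 or 16 hpf, morpholino replicate 1 at 12, 13 or 14 hpf, replicate 2 at 13, 15 or 16 hpf, or replicate 3 at 16 hpf.

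**Figure D2:**
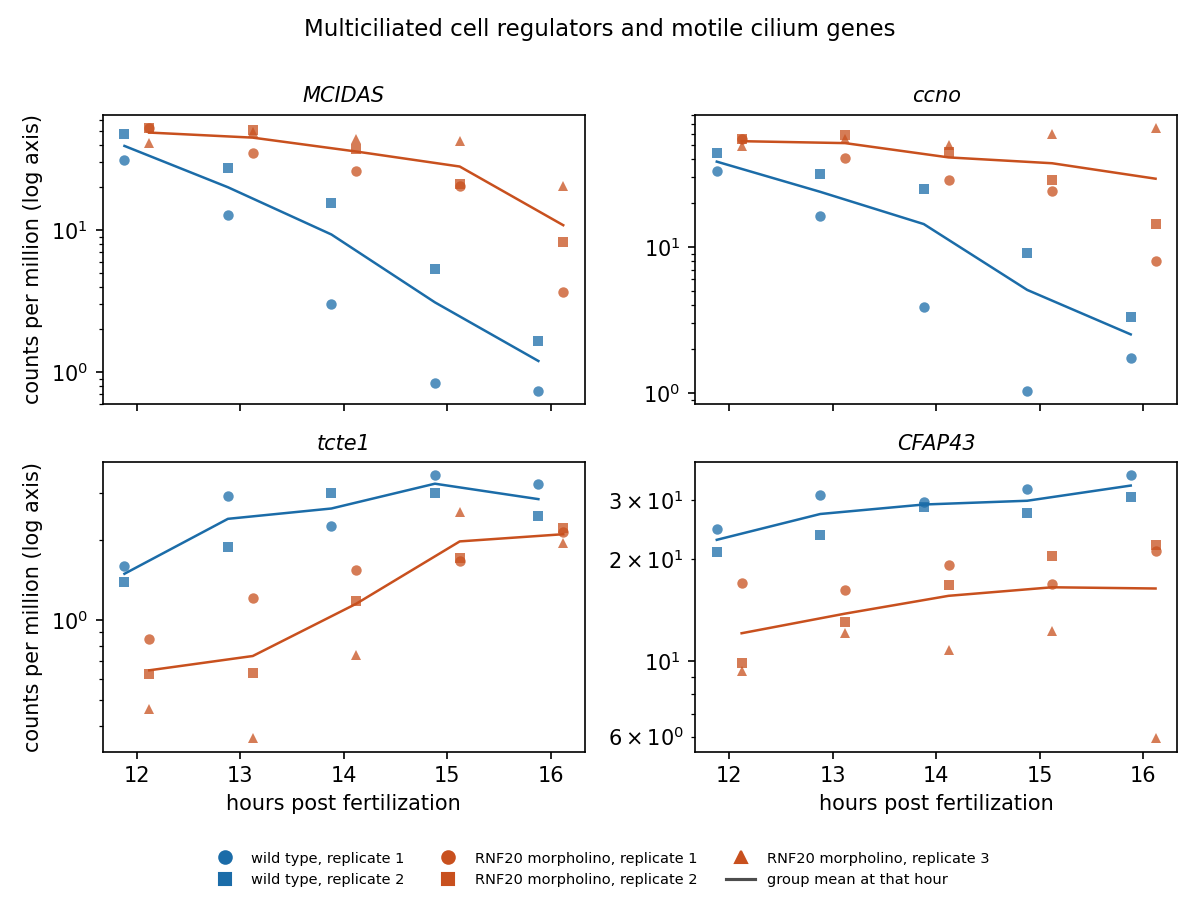
CPM (log axis) against hours post fertilization for the multiciliated cell regulators MCIDAS and ccno and the axonemal genes tcte1 and CFAP43, with a point per library (shape gives the replicate number) and a line through the group mean at each hour. MCIDAS and ccno declined in wild type and stood higher in the morpholino arm, by log2 averages of 1.95 and 1.91, while tcte1 and CFAP43 stood lower.

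Camera called the maternal, axis patterning and cell cycle lists higher in the morpholino libraries. With the arm labels redrawn within hours, 9, 7 and 31 of 100 draws gave these lists as small a p. Of 41 maternal and germ plasm transcripts, 18 rose and 1 fell (24 and 1 adjusted over the list alone). Maternal transcripts rose as a list in camera (adjusted p = 3.44e-06), with adjusted p = 0.596 with an estimated correlation. The pluripotency factor pou5f3.1 rose by 2.44 ± 0.52, the egg coat gene zp4 by 0.93 ± 0.14 and the germ plasm gene tdrd6 by 0.80 ± 0.14 (SE, edgeR adjusted p = 0.0038, 3.98e-04 and 8.18e-04). Of 49 axis patterning signals and targets, 22 rose and 3 fell (26 and 3 adjusted over the list alone). The axis list also rose in camera (adjusted p = 3.44e-06), with adjusted p = 0.596 with an estimated correlation. Its risen members included the FGF feedback phosphatase dusp6 (0.55 ± 0.06) and the retinoic acid enzyme aldh1a2 (0.86 ± 0.14, SE, edgeR adjusted p = 1.95e-05 and 5.17e-04). Of 50 cell cycle transcripts 14 rose and 3 fell, also adjusted over the list alone. The cell cycle list rose in camera (adjusted p = 0.0058), with adjusted p = 0.619 with an estimated correlation. Here the replication helicase mcm3 rose by 1.96 ± 0.31 while the mitotic phosphatase cdc25c fell by 0.73 ± 0.10 and the spindle checkpoint kinase bub1b fell by 0.38 ± 0.07 (SE, edgeR adjusted p = 4.45e-04, 9.93e-05 and 0.00236). The maternal and axis lists passed without morpholino replicate 3 (camera adjusted p = 2.18e-04 for each, and adjusted p = 0.801 with an estimated correlation), and the cell cycle list did not (0.276). There the risen maternal transcripts had a median of 0.678 (1.29 with all libraries), with 11 of 16 still called, the risen axis transcripts 0.439 (0.695), with 19 of 22 still called, and pou5f3.1 stood at 1.27. None of the 3 passed against wild type 2 hours earlier (camera adjusted p = 0.526 for maternal, 0.387 for axis and 0.653 for cell cycle transcripts), with 0 of 18, 1 of 22 and 0 of 14 risen transcripts still called (6, 7 and 4 against wild type of the same hour at 14 to 16 hpf). With that earlier wild type pou5f3.1 stood at 1.06, zp4 at 0.60, tdrd6 at 0.21, aldh1a2 at 0.31, mcm3 at 1.14 and bub1b at -0.24 (edgeR adjusted p from 0.106 to 0.647), while dusp6 (0.57) and cdc25c (-0.86) stayed called (adjusted p = 6.23e-04 and 9.23e-04). With wild type 1 hour earlier zp4, tdrd6, aldh1a2, mcm3 and bub1b stayed called (edgeR adjusted p from 0.00957 to 0.04). There pou5f3.1 did not (1.83, edgeR adjusted p = 0.062). Over all alternatives the adjusted p ran from 1.39e-07 to 0.596 for the maternal list, from 4.9e-07 to 0.596 for the axis list and from 0.00304 to 0.653 for the cell cycle list.

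With all libraries none of the germ layer and tissue lists passed camera, though members of each changed. Over all 16967 tested transcripts 4581 were called, 2353 higher and 2228 lower. Called members alone therefore do not set a list apart, here or above. Of 37 heart and cardiac mesoderm transcripts 9 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0506, and 0.0372 to 0.0487 on leaving out any of 8 libraries). Over all alternatives the camera adjusted p of the heart list ran from 0.0313 to 0.63, and no list was called with an estimated correlation. The cardiac regulator nkx2-5 fell by 0.78 ± 0.17 and the myosin light chain myl4 by 2.08 ± 0.44 (SE, edgeR adjusted p = 0.00417 and 0.00372). Against wild type 2 hours earlier nkx2-5 stood at -0.27 and myl4 at 0.45 (edgeR adjusted p = 0.63 and 0.792), and of the 9 fallen heart transcripts 0 were still called (median -0.00969, with 2 still called and a median of -1.13 against wild type of the same hour at 14 to 16 hpf). A transcript of the limb and heart factor tbx5 fell from 0.575 ± 0.415 CPM (SD, n = 10) to 0.155 ± 0.206 CPM (SD, n = 15; edgeR adjusted p = 0.00824, and 0.633 for this tbx5 transcript against wild type 2 hours earlier). Of 31 left-right and Nodal transcripts 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.193). The Nodal co-receptor tdgf1.3 rose by 3.33 ± 0.62 and mmp21 by 1.22 ± 0.29 (SE, edgeR adjusted p = 0.00152 and 0.00742), but stood at 1.57 and 0.63 against wild type 2 hours earlier (adjusted p = 0.339 and 0.482). Without morpholino replicate 3 they stood at 2.23 and 0.70, both still called (edgeR adjusted p = 0.00231 and 0.0118). Nodal itself, at 0.0767 ± 0.0912 CPM (SD, n = 10) in wild type, stood at 2.84 ± 0.83 (SE, edgeR adjusted p = 0.0198, from 0.00292 to 0.707 over all alternatives). The nodal call ended against wild type 2 hours earlier (adjusted p = 0.549), without all of morpholino replicate 3 (0.246), without wild-type replicate 1 at 14 hpf (0.0507) and without morpholino replicate 3 at 16 hpf (0.060).

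Of 27 endoderm transcripts 11 rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.053, and 0.0355 to 0.048 on leaving out any of 9 libraries). Over 14 to 16 hpf alone the endoderm list was called (camera adjusted p = 0.0146), with adjusted p = 0.366 with an estimated correlation. The maternal endoderm determinant vegt rose by 1.94 ± 0.37 and the pancreatic factor pdx1 fell by 1.75 ± 0.29 (SE, edgeR adjusted p = 0.00186 and 7.51e-04). Vegt stood at 0.67 and pdx1 at -0.50 against wild type 2 hours earlier (edgeR adjusted p = 0.554 and 0.598). Of 37 paraxial mesoderm and muscle transcripts 7 rose and 7 fell (8 and 10 adjusted over the list alone, camera adjusted p = 0.364). The Notch ligand dll1 rose by 0.51 ± 0.10 (SE, edgeR adjusted p = 0.00187), and muscle creatine kinase ckm fell from 23.5 ± 20.4 CPM (SD, n = 10) to 8.69 ± 8.32 CPM (SD, n = 15, edgeR adjusted p = 0.00474), though against wild type 2 hours earlier ckm stood at 0.15 (adjusted p = 0.934). Of 25 notochord and organizer transcripts 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.364, up, with a list median of -0.02). Its largest rises included the secreted Wnt antagonist frzb (2.31 ± 0.49) and foxa4 (1.02 ± 0.24, SE, edgeR adjusted p = 0.00392 and 0.00651). Of 65 neural plate and neuron transcripts 9 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.110). The neuronal genes elavl4 and ebf2 fell by 2.08 ± 0.39 and 0.90 ± 0.18 (SE, edgeR adjusted p = 0.0018 and 0.00242), and against wild type 2 hours earlier stood at -0.57 and -0.10 (adjusted p = 0.665 and 0.911). Of 39 neural crest and placode transcripts 3 rose and 5 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.754). The placode factor eya2 fell by 0.38 ± 0.07 (SE, edgeR adjusted p = 0.00152), a change not seen against wild type 2 hours earlier (-0.00377, adjusted p = 1). In that comparison dll1 stood at 0.24, frzb at 1.51 and foxa4 at 0.31 (edgeR adjusted p = 0.414, 0.254 and 0.703). Without morpholino replicate 3 frzb stood at 1.18, foxa4 at 0.61 and vegt at 1.13, each still called (edgeR adjusted p from 1.56e-04 to 0.00682).

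Of 43 epidermal, ionocyte and secretory transcripts 6 rose and 6 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.761). The ionocyte factor foxi1 rose by 1.05 ± 0.14 (SE, edgeR adjusted p = 1.16e-04). Of 25 blood and endothelial transcripts 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.134). The endothelial receptor kdr fell by 1.05 ± 0.29 (SE, edgeR adjusted p = 0.015). Of 23 transcripts of the H2B ubiquitination machinery 5 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0506, and 0.0344 to 0.0489 on leaving out any of 13 libraries). Over all alternatives the camera adjusted p of this list ran from 0.0233 to 0.745. The deubiquitinase usp7 rose by 0.46 ± 0.10 (SE, edgeR adjusted p = 0.0057). Of 18 dynein arm assembly transcripts 1 rose and 3 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.754, down, with a list median of 0.02). The assembly factor spag1 went both ways, with transcripts at 0.56 ± 0.08 and -0.53 ± 0.07 (SE, edgeR adjusted p = 1.15e-04 and 1.78e-04). Of 42 intraflagellar transport transcripts 3 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.220). Ift20 rose by 0.47 ± 0.06 and ttc21b fell by 0.53 ± 0.12 (SE, edgeR adjusted p = 9.93e-05 and 0.00631). Of 54 BBSome and transition zone transcripts 9 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.0821). The transition zone gene tmem216 fell by 0.61 ± 0.14 (SE, edgeR adjusted p = 0.00496). Of 26 interferon and innate immune transcripts 5 rose and 1 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.520, up, with a list median of -0.03). The interferon factor irf1 rose by 0.80 ± 0.14 (SE, edgeR adjusted p = 9.77e-04). Foxi1, ift20, irf1 and the risen spag1 transcript stayed called against wild type 2 hours earlier (edgeR adjusted p from 0.0138 to 0.0363). In that comparison the calls of kdr (-0.23), usp7 (0.25), ttc21b (-0.43), tmem216 (-0.18) and the fallen spag1 transcript (-0.37) ended (edgeR adjusted p from 0.0554 to 0.856).

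Across all transcripts, 4581 passed in the average comparison, 2353 higher and 2228 lower in the morpholino arm (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Of these 1324 changed by over 1 log2 unit, and limma-voom put 2021 of its 5017 calls higher. The glial glutamate transporter slc1a3 fell by 2.77 ± 0.52 and the matrix gene cilp fell by 3.03 ± 0.64 (SE, edgeR adjusted p = 0.00157 and 0.00377). For slc1a3 this was a fall from 133 ± 98.7 CPM (SD, n = 10) to 25.8 ± 34.4 CPM (SD, n = 15). Against wild type 2 hours earlier slc1a3 stood at -0.63 and cilp at 0.46 (edgeR adjusted p = 0.728 and 0.842). Many of the largest fitted changes belonged to transcripts at 0 in several libraries. The actn1 transcript with the largest rise (6.97 ± 1.72, SE, edgeR adjusted p = 0.0104) lay at 0 in 8 of 10 wild-type libraries, and actn1 counts summed over its transcripts stood at 0.10 (edgeR adjusted p = 0.272). In the same way the sema3f transcript with the largest fall, -4.64 ± 1.13 (SE, edgeR adjusted p = 0.0108, and 1 without wild-type replicate 2 at 12 hpf), became -0.20 (edgeR adjusted p = 0.116) per symbol, so such transcripts are reported as uncertain. With same-numbered libraries of an arm summed over the hours into 5 sums, edgeR called 0 transcripts (1814 at an unadjusted p under 0.05; no other tool was run on the sums), and ccng1 and rpap3 each had an adjusted p of 0.171. The count was 2867, 2844, 2933, 2963 and 3047 without wild-type replicate 1 at 12, 13, 14, 15 and 16 hpf, 3424 with the replicate number as a block (3060 of them among the 4581) and 379 against wild type 2 hours earlier, where 1 list, that of p53 targets, passed (camera adjusted p = 0.0023, and adjusted p = 0.144 with an estimated correlation). That comparison sets morpholino libraries of 14 to 16 hpf against wild type of 12 to 14 hpf, 9 against 6 libraries, and the same 9 against wild type of their own hours gave 1387 (1354 of them among the 4581). Of the calls given above as ended against wild type 2 hours earlier, those of tcte1, efhc2, foxj1, bub1b, nkx2-5, nodal, pdx1, ebf2, eya2, kdr, usp7, tmem216 and cilp also ended there (edgeR adjusted p from 0.0506 to 0.223), so the loss of these calls does not rest on the earlier reference alone. Against wild type 1 hour earlier rnf40, tdgf1.3, vegt, pdx1, dll1, frzb and the fallen spag1 stayed called (edgeR adjusted p 0.0029 to 0.0474). There mmp21, nkx2-5, myl4, tbx5, ckm, foxa4, elavl4, ebf2, eya2, kdr and nodal were not called (edgeR adjusted p 0.0595 to 0.228). Nor were usp7, ttc21b, tmem216, slc1a3, cilp and foxj1 (edgeR adjusted p 0.0574 to 0.231). A further limit is that 43 of 100 redraws of the arm labels within hours called as many lists as the 7 called here.

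Hour by hour, with 3 morpholino against 2 wild-type libraries, the same few transcripts passed at each hour. Ccng1 rose by between 1.72 (15 hpf) and 2.09 (12 hpf) and rpap3 fell by between 1.78 (13 hpf) and 2.25 (14 hpf) on the log2 scale, passing in edgeR at all 5 hours. Dedd, riok3, pdlim7 and lmnb3 also passed at all 5 hours. The p53 target eda2r passed at 14 hpf (3.51), aen at 14 and 15 hpf (1.44 and 1.54), and the centriolar satellite gene pcm1 at 14, 15 and 16 hpf (1.11, 1.12 and 1.19). The fatty acid transporter slc27a2 fell by 2.08 at 13 hpf and the ubiquitin ligase adaptor klhl25 by 2.19 and 2.09 at 15 and 16 hpf. In all, edgeR called 8, 15, 21, 16 and 34 transcripts from 12 to 16 hpf, with 4, 5, 11, 8 and 22 of them higher. Without wild-type replicate 1, then 2, and morpholino replicate 1, 2, then 3 of the hour, the counts were 0, 3, 5, 1 and 2 at 12 hpf, 1, 0, 1, 1 and 4 at 13 hpf and 1, 10, 13, 7 and 4 at 14 hpf. At 15 hpf they were 5 and 0 without wild-type replicate 1 and 2 and 7 without morpholino replicate 1 or 3, and at 16 hpf 5 and 0 without wild-type replicate 1 and 2 and 55 without morpholino replicate 2. Without morpholino replicate 3 the counts were 730, 2241, 638, 526 and 390, and with the 5 libraries of the hour alone edgeR called 0 at each hour. With the replicate number as a block it called 167, 761, 187, 191 and 188. On all libraries, 1355, 2194, 1420, 1629 and 2066 transcripts had an unadjusted p under 0.05 in edgeR, and DESeq2 called 157, 266, 175, 259 and 335.

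In the authors' deposited tables, made with sleuth for each hour, 129, 911, 167, 99 and 7 transcripts had a q-value under 0.05 from 12 to 16 hpf. All of those in the authors' deposited tables had the same sign in the edgeR fit of that hour, and 8, 15, 18, 12 and 2 of them were also called there. Both analyses rest on the same counts. The direction of the deposited effects was matched to those counts, so the shared sign is no independent check. In the average comparison 129, 825, 146, 92 and 7 of the transcripts in the authors' deposited tables were called.

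No transcript had a morpholino effect that differed between hours after adjustment: edgeR called 0, with 166 at an unadjusted p under 0.05, while limma-voom called 1 and DESeq2 called 2. Among the smallest unadjusted p values, a yju2 transcript, which encodes a splicing factor, ran from 0.26, 0.51 and 0.42 at 12 to 14 hpf to 1.87 at 15 hpf and -0.19 at 16 hpf on the log2 scale. The edgeR count was 1 without morpholino replicate 1 at 14 hpf and 1 without wild-type replicate 1 at 16 hpf.

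In wild type, 12 of 39 transcripts on the list of multiciliated regulators declined from 12 to 16 hpf, while col1a1, myl4 and hba3 increased. MCIDAS fell by 1.28 ± 0.21 log2 units per hour, CDC20B by 1.02 ± 0.17 and the BMP family signal admp by 1.04 ± 0.26 (SE, edgeR adjusted p = 0.00802, 0.00802 and 0.0422). The collagen col1a1 rose by 1.57 ± 0.32 per hour, myl4 by 1.44 ± 0.28 and the haemoglobin gene hba3 by 1.35 ± 0.32 (SE, edgeR adjusted p = 0.0198, 0.0156 and 0.0366). The ciliary and multiciliated transcription list declined, with 12 of 39 transcripts falling and 0 rising (13 and 0 adjusted over the list alone). Its camera adjusted p was 9.93e-08, with adjusted p = 0.0859 with an estimated correlation. The p53 list, with 1 of 38 transcripts rising and 0 falling, was not called (camera adjusted p = 0.999). In all 371 transcripts changed, 202 rising and 169 falling. The arms share an estimate of the spread, so this count also depends on the scatter of the morpholino libraries. A fit of the wild-type libraries alone called 7018, and 3266 passed with the replicate number as a block within each arm (3484 with it as a block over both). The count was 42, 8, 63, 70, 15 and 109 without wild-type replicate 1 or 2 at 12 hpf, replicate 2 at 13 hpf, replicate 1 at 15 hpf or replicate 1 or 2 at 16 hpf, 685 and 2114 without morpholino replicate 3 at 15 or 16 hpf, and 6712 without all of morpholino replicate 3.

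In the morpholino arm 19 of the 79 nexin link, spoke and doublet transcripts rose with time and 0 fell (21 and 0 adjusted over the list alone). The camera adjusted p of these axonemal transcripts was 1.70e-08, with adjusted p = 0.396 with an estimated correlation. Tcte1 rose by 0.48 ± 0.09 log2 units per hour (SE, edgeR adjusted p = 0.00411) against 0.23 ± 0.11 in wild type (SE, adjusted p = 0.233). MCIDAS fell by 0.50 ± 0.15 per hour and nkx2-5 rose by 0.40 ± 0.08 (SE, edgeR adjusted p = 0.0262 and 0.00438). Blood and endothelial transcripts increased, with 12 of 25 rising and 2 falling (16 and 3 adjusted over the list alone). Their camera adjusted p was 8.5e-05, with adjusted p = 0.396 with an estimated correlation, and hba3 rose by 1.68 ± 0.30 per hour (SE, edgeR adjusted p = 0.00302). In all 2996 transcripts changed, 1766 rising and 1230 falling (limma-voom, 1338 rising of 2741). The count was 1460, 1013 and 6026 without morpholino replicate 2 or 3 at 12 hpf or replicate 3 at 16 hpf, 7509 without all of replicate 3 and 5562 with the replicate number as a block within each arm (5825 with it as a block over both).

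Placed on the wild-type time line by 7016 transcripts that changed in a fit of the wild-type libraries alone, morpholino libraries lay 1.86 hours earlier than wild type of the same hour (difference -1.86 hours, two-sided permutation test within hours over the 100000 exact arrangements, p = 2.9e-04). Wild-type libraries lay at -0.00871 ± 0.651 hours from their own collection time (SD, n = 10) and morpholino libraries at -1.87 ± 1.15 hours (SD, n = 15). The morpholino series differed among themselves, with replicate 1 at -0.899 ± 0.396, replicate 2 at -1.45 ± 0.197 and replicate 3 at -3.25 ± 0.824 hours (SD, n = 5 each). The wild-type series lay at 0.571 ± 0.288 for replicate 1 and -0.589 ± 0.174 hours for replicate 2 (SD, n = 5 each). Taken as 5 series, 3 against 2, the exact p was 0.2, and that design cannot give a p below 0.1. Without replicate 3 the difference was -1.16 hours. All replicate 3 libraries and those of morpholino replicates 1 and 2 at 12 and 13 hpf were placed below 12 hours. So was wild-type replicate 2 at 12 hpf. These placements extend the straight wild-type line beyond its hours, so their size is uncertain.

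**Figure D3:**
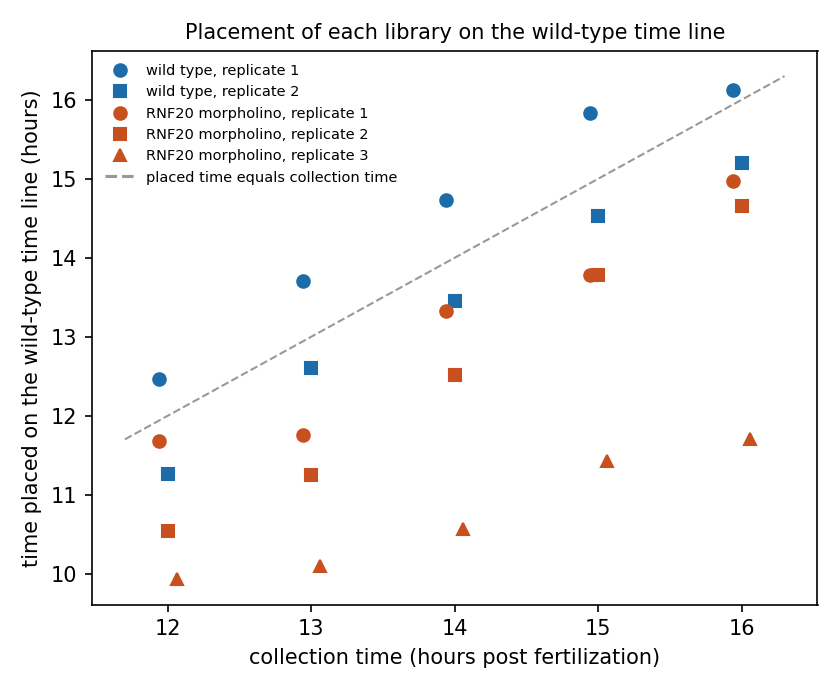
Time at which each library was placed on the wild-type time line (hours) against its collection time (hours post fertilization), with a point per library, shape giving the replicate number and the dashed line marking equality. The morpholino replicate 3 libraries were placed at 9.93 to 11.7 hours, below all other libraries of their hour. Wild type was sampled from 12 hpf, so placements below 12 hours extend its straight line beyond the data.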

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

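The opposite directions given here were noticed after the results were seen and were not tested, apart from the comparison of the effect between hours, in which edgeR gave each of these transcripts an adjusted p of 1. A bhlhe40 transcript, from a gene for a clock-linked repressor, stood at 8.72 log2 units higher in the morpholino libraries at 14 hpf and at -8.57 at 16 hpf. Both wild-type libraries at 14 hpf and all 3 morpholino libraries at 16 hpf lay at 0, so neither size has a bound. Over all hours it lay at 0 in 3 of 10 wild-type and 4 of 15 morpholino libraries, and its symbol has 2 tested transcripts. A transcript of the chromatin remodeller rad54l2 stood at 1.11 at 13 hpf, at -1.07 at 14 hpf and at 3.85 at 16 hpf. The protease gene prss29 stood at 0.39 and 0.17 at 12 and 13 hpf and at -1.01 and -1.62 at 15 and 16 hpf. With 2 wild-type and 3 morpholino libraries per hour, these differences between hours remain untested as single changes.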

How the results depend on the processing

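The alternatives without morpholino replicate 3, against wild type of earlier hours, at 14 to 16 hpf only, on 5 sums, with a block per arm and with thinned counts were chosen after the data were seen. A fit with an effective-length offset was not run, because effective lengths were identical in all libraries. The cause was not tested for any of the shifts given here unless the text says otherwise.

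The average morpholino effect, with 4581 calls, gave 1666 at an adjusted p under 0.01, 1015 against wild type 1 hour earlier, 379 against wild type 2 hours earlier (338 of them among the 4581), 1387 against wild type of the same hour at 14 to 16 hpf (1354 of them among the 4581) and 3027 against wild type 1 hour earlier without the morpholino replicate 3 libraries. Without the morpholino replicate 3 libraries edgeR called 6134, 4065 of them among the 4581. On 5 sums of same-numbered libraries edgeR called 0 (1814 at an unadjusted p under 0.05). Without the libraries at 12, 13, 14 or 15 hpf it called 2878, 1739, 2612 and 2795. Leaving out a library gave 2844 to 5795. The comparison with wild type 2 hours earlier uses the same 9 morpholino libraries as that at 14 to 16 hpf, so the step from 4581 to 1387 comes with the hours used and the step to 379 with the earlier reference.

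For the hours, an adjusted p under 0.01 left 1, 2, 4, 7 and 5 calls from 12 to 16 hpf. Without a filter the count was 7 at 13 hpf, 13 at 14 hpf and 20 at 16 hpf, and with at least 10 CPM in 2 libraries it was 21 at 12 hpf, 25 at 15 hpf and 54 at 16 hpf. Limma-voom called 9 at 14 hpf and 47 at 15 hpf, and DESeq2 called 157, 266, 175, 259 and 335. Without the morpholino replicate 3 libraries edgeR called 730, 2241, 638, 526 and 390, and with the 5 libraries of that hour alone 0 at each hour. Leaving out a library gave 0 to 5, 0 to 4, 1 to 13, 0 to 13 and 0 to 55.

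With the replicate number as a block, edgeR called 3424 transcripts in the average effect (3060 of them among the 4581), 167, 761, 187, 191 and 188 transcripts from 12 to 16 hpf, and 3484 for the wild-type and 5825 for the morpholino change over time. A replicate block per arm gave 3266 and 5562. The arms share an estimate of the spread, and without morpholino replicate 3 the wild-type count was 6712 with no block. The higher blocked count for the wild-type slope can therefore not be credited to the pairing of the wild-type series alone.

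The wild-type change over time, with 371 calls, gave 31 at an adjusted p under 0.01, 723 by limma-voom, 1521 by DESeq2, 6712 without the morpholino replicate 3 libraries and 8 to 2114 on leaving out a library. The morpholino change over time, with 2996, gave 704 at an adjusted p under 0.01, 7509 without the morpholino replicate 3 libraries and 1013 to 6026 on leaving out a library. For the effect differing between hours edgeR called 0, limma-voom 1 and DESeq2 2, and leaving out a library gave 0 to 1.

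Camera called 7 gene lists. It called 0 with an estimated correlation, 4 without the morpholino replicate 3 libraries, 4 against wild type 1 hour earlier, 1 against wild type 2 hours earlier, 7 at 14 to 16 hpf only (with endoderm, camera adjusted p = 0.0146, and adjusted p = 0.366 with an estimated correlation, in place of the dynein arms, 0.168) and 6 to 10 on leaving out a library. Against wild type 1 hour earlier without replicate 3 it called 2, the p53 targets and the list of neural plate and neurons (down, camera adjusted p = 0.00647, and adjusted p = 0.655 with an estimated correlation), which was not among the 7. Of the 7 lists, 2 turned direction: against wild type 2 hours earlier the list of ciliary and multiciliated transcription went down (adjusted p = 0.526), as did the cell cycle list (0.653), which also went down against wild type 1 hour earlier without replicate 3 (0.243). Lists not called also turned, among them left-right patterning (0.884) and notochord (0.893) against wild type 2 hours earlier. The stage index of -1.86 hours was -1.96 to -1.60 hours on leaving out a library, -1.26 hours on genes not called and -1.16 hours without the morpholino replicate 3 libraries.

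The rnf20 level of 0.31 lost its call against wild type 2 hours earlier (0.42), on 5 sums (0.29), at 14 to 16 hpf only (0.0379) and without the libraries at 12 hpf (0.18) or 13 hpf (0.26), and leaving out a library gave 0.28 to 0.35.

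Some named transcripts turned direction. With counts summed per symbol these were tle2 (-0.998), cgnl1 (-0.13), spag1 (-0.13), pax2 (-0.32), rfx3 (-0.95) and nkx2-5 for its minor transcript (-0.76). Against wild type 2 hours earlier they were vps4b (-0.42), ADGRD2 (0.81), pdlim3 (0.55), cybb (0.65), cilp (0.46), nt5c1b (0.15), col1a1 (0.48), myl4 (0.45), smarcd3 (0.0163), ckm (0.15), hba3 (0.89), yju2 (-0.0630), egfl7 (1.303), egr4 (-0.38) and CDC20B (-0.11). Against wild type 1 hour earlier without replicate 3 they were egfl7 (0.37) and egr4 (-0.13).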

Other observations

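Tests chosen after the result was seen were those of replicate 3 and of series timing for the stage index, of a general morpholino response and of RNA quality. Redrawn labels for the list count and for single lists, and series splits for single lists, were also chosen then. So was each comparison with earlier wild type, at 14 to 16 hpf only, without replicate 3, on 5 sums or with thinned counts. The ionocyte gene ubp1 rose by 1.14 ± 0.15 (SE, edgeR adjusted p = 9.28e-05) and gata2, which acts in epidermis and blood, by 1.11 ± 0.25 (SE, edgeR adjusted p = 0.00507). The Nodal partner gdf3 rose by 1.05 ± 0.21 and the somite factor mespb by 0.92 ± 0.22 (SE, edgeR adjusted p = 0.00262 and 0.00645). Against wild type 2 hours earlier ubp1 stayed called (0.87, edgeR adjusted p = 0.0216), while gata2 (0.60), gdf3 (0.12) and mespb (0.19) did not (adjusted p = 0.414, 0.908 and 0.819), mespb also not at 14 to 16 hpf with wild type of the same hour (adjusted p = 0.0777). Among transcripts with the same sign at each hour, the protein kinase prkcd fell by 0.85 ± 0.08 and the ubiquitin ligase gene march8 rose by 1.32 ± 0.19 in 1 of its 2 transcripts (SE, edgeR adjusted p = 4.83e-06 and 2.43e-04), where against wild type 2 hours earlier prkcd stayed called (-0.81, adjusted p = 3.81e-04) and march8 did not (0.66, adjusted p = 0.204). With wild type 1 hour earlier march8 stayed called (1.01, edgeR adjusted p = 0.0093). There gata2, gdf3 and mespb were not called (edgeR adjusted p from 0.073 to 0.116).

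Redrawing the arm labels within hours gave as many calls as the 4581 of the average effect in 1 of 60 draws, the real labels included (highest other 1). These draws break up the series. They exclude chance only if the libraries were independent, which the correlations within a series go against. The 5 embryo series make 10 splits into 3 and 2, for which the share cannot go under 0.05. Of these, 2 gave as many calls, with 4581 for the real split and a highest other of 6737, where morpholino replicates 2 and 3 were set apart, which points to a structure among the series. RNA quality may also differ between the arms and cannot be told apart from an effect of the morpholino, since at 5 of 5 hours each morpholino library had a higher mitochondrial share than each wild-type library.

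Morpholino libraries lay 1.86 hours early on the wild-type time line. Unequal depth was argued against, since the difference was -1.81 hours after thinning each library to the same depth. Without morpholino replicate 3 the difference was still -1.16 hours (exact permutation p = 0.00129), so the shift of these libraries did not come from that replicate alone. That permutation breaks up the series, so its p holds only if the libraries were independent. By series, morpholino replicate 1 lay at -0.899 and wild-type replicate 2 at -0.589 hours. Embryo series that differ in timing without the morpholino cannot be told apart from its effect, because the wild-type series themselves lay 1.16 hours apart and 5 series cannot give a p under 0.1. A slower development of injected embryos may account for the shift, and these values do not separate it from the timing of the series.

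The p53 targets called higher had a median log2 change of 0.974 over 13 transcripts. Against wild type 2 hours earlier the median was 0.794 ± 0.14 (SE), with 6 of 13 still called (1.09 and 8 against wild type of the same 14 to 16 hpf), and a developmental delay would have taken it under 0.5 of its size. The bound set beforehand for arguing against a delay was 0.75 of its size. The median stood at 81.6% of that over all hours, but at 72.7% of that over the same 14 to 16 hpf, short of the bound. Without morpholino replicate 3 the median was 0.699 ± 0.098 (SE), with 12 still called, which argues against that replicate as the whole source, though it did not stay above the 0.75 of its size set beforehand. Over all transcripts 4065 of the 4581 calls also stayed, so the count still called does not set this list apart. Redrawn labels gave the list as small a p in 2 of 100 draws (real p = 0.00125, smallest other 1.32e-04 in these permutation draws), a share of 0.42 after adjustment over 21 lists. These draws also break up the series, so they do not exclude chance for this list. Of 10 splits of the 5 series only the real 1 gave as small a p (smallest other p 0.0104), too few splits to exclude chance between series. A general response to injected morpholino may explain the rise and cannot be told apart from an effect of RNF20, since 0 libraries with another morpholino were analysed here.

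Transcripts for the axoneme and dynein arm assembly called lower had a median of -0.708 over 24 transcripts, 3 of them for assembly, and the 11 called regulators of multiciliated cells a median of 0.81. Without morpholino replicate 3 the median of the 24 was -0.527 ± 0.13 (SE), with 20 of 24 still called, which argues against that replicate as the whole source, though it also fell short of 0.75 of its size. The 24 were chosen by their calls with these same libraries, and 4065 of all 4581 calls stayed, so that count does not set them apart. Against wild type 2 hours earlier the median of the 24 was -0.35 ± 0.11 (SE) with 0 still called, and the regulators' median 0.249 ± 0.21 (SE) with 1 still called, where wild type of the same 14 to 16 hpf gave -0.612 with 4 and 0.791 with 7 still called. A developmental delay may therefore account for at least part of both, and cannot be told apart from a direct effect. Each value lay within its error of 0.5 of the median over all hours (-0.708 and 0.81). This use of the error was set after the medians were seen. By the bound written beforehand, under 0.5 of those medians, both met the delay. Of the medians over the same 14 to 16 hpf the values were 57.3% and 31.4%, so there only the regulators fell under 0.5. Wild-type slopes had a median of 0.102 log2 units per hour for the 24 and -0.299 for the regulators. A delay therefore predicts a smaller shift for the 24. The same 2-hour shift was used for all series, though on the time line morpholino replicates 1, 2 and 3 lay at -0.899, -1.45 and -3.25 hours. Redrawn labels called as many as the 7 lists in 43 of 100 draws (highest other 12), so chance cannot be excluded for the count of lists. For single lists they gave as small a camera p in 35 draws for the nexin link and spoke list and 43 for the dynein arms. The draws numbered 21 for multiciliated regulators, 31 for cell cycle, 9 for maternal and 7 for axis transcripts. Of the 10 series splits, 4, 5, 2, 8, 3 and 4 gave these lists, in that order, as small a p. Chance is therefore not excluded for any of these lists.

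Hours drawn at random over the morpholino libraries gave as many calls as the 2996 of the morpholino change over time in 1 of 60 draws, the real one included (highest other 1248). These draws also break up the series, so they exclude chance only if the libraries were independent. A split that keeps each series whole was not run for this comparison.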
